A study of Drosophila melanogaster with 4 samples.

How the data were processed

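H3K9ac, the acetylated lysine 9 of histone H3 that is found at active promoters, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster embryos aged 14 to 16 h of the wild-type strain Oregon-R. Per the labels, the series has 4 samples: H3K9ac ChIP replicates 1 and 2, and input chromatin replicates 1 and 2. Per the labels' protocols, embryos were fixed with formaldehyde and the antibody-bound chromatin was recovered on protein A beads. The labels name the ChIP list that each input served, and no values of the inputs themselves were used here. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

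The deposited files are 3 lists of regions that the authors called significantly enriched, termed clusters below. There is one list for each ChIP replicate and one series-wide list for the replicate set. Per the file headers, coordinates refer to FlyBase release 5 of the genome, and coordinates are given here as in the files, counted from 1. Each cluster carries a score, deposited by the authors in column 6 of the files. What the score is relative to, the caller and its threshold, the aligner, and the way the replicates were combined in the series-wide list are not given in the sources used here. The scores were used to rank or filter clusters within a list and for the planned rank correlation between the replicates. Ratios of X to autosome scores within a list appear in the closing section alone, and the zero of the score they would need is unknown. Read depth per sample is unknown, so no value below has an interval for read sampling. The 95% Wilson or exact binomial intervals on shares of clusters, and the exact intervals on ratios of cluster densities, cover counting error alone.

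Covered bases were counted after merging overlapping clusters and divided by the sequence lengths in the file headers, without the unplaced Uextra collection, which held 0 clusters. The large arms are X, 2L, 2R, 3L and 3R, the autosome arms are the last 4 of these, and the heterochromatic scaffolds are 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet. Clusters were counted as shared when they overlapped by at least 1 bp. Agreement of the replicates was tested against 1000 random placements of the clusters of one list within their own chromosome, without overlap among them. The one-sided permutation p cannot be smaller than 0.001. Random placement takes any assembled base as equally open to a cluster, although mappability was not modelled. Spacing between neighbouring clusters was tested with the same kind of placement.

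Each arm was also divided into bins of 1 Mb, of which 117 were complete. X and autosome bins were compared by a two-sided permutation test with 100000 resamples, and the 6 p-values of that family were adjusted by the Benjamini-Hochberg method. Bins of one genome are neighbours, not biological replicates, so these p-values describe the lists and are too small where adjacent bins resemble each other. With 2 replicates, no exact permutation test on the replicate values can reach p under 0.05, and such values are given with their SD. Score percentiles are ranks within one list. The code for overlaps and placements was tested on simulated data. For 8495 simulated clusters, the share that was copied on purpose was recovered to within 0.353 percentage points. The copies were shifted by less than a cluster width and no unrelated clusters were added. Each copy had to overlap its source, so the recovery checks the overlap count alone. Of 40 unrelated pairs of lists, 3 gave p at or under 0.05.

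Tests, alternatives and the rule for the regions to be named were set before the data were examined, except where stated. The comparisons over bins, of score percentiles between X and autosomes, by score decile and of cluster boundaries were chosen afterwards. The rule took the 10 highest-scoring and the 5 widest clusters of the series-wide list, and the 5 highest-scoring clusters of each replicate that the other did not overlap. The gene table at hand belongs to Release 6 of the genome, and coordinates were not converted between releases. Regions are therefore named by position. Of the planned results, 3 were not computed for this reason: the share of clusters at transcription starts, the share of genes marked, and the comparison of 35 gene lists. Alternatives tried were a 50% overlap, clusters at or above the median score of their list, the large arms alone, clusters per megabase, each replicate alone, other ways of pairing scores, and the series-wide list. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.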

Results

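H3K9ac was profiled by ChIP-seq in embryos of the wild-type fly strain Oregon-R at 14 to 16 h of development, with 2 ChIP samples and 2 input samples. The list of ChIP replicate 1 held 8495 enriched clusters that covered 24.8 Mb, or 17.8% of the 139.7 Mb assembled genome. The list of ChIP replicate 2 held 6772 clusters that covered 17.5 Mb, or 12.5%. The series-wide list was longer than either, with 12322 clusters over 34.0 Mb, or 24.4%. The median cluster was 2300 bp wide in replicate 1, 2190 bp in replicate 2 and 2077 bp in the series-wide list. The narrowest cluster of each replicate was 1301 bp, and the series-wide list held narrower ones. Scores, as deposited by the authors, had a median of 0.672 in replicate 1, 0.814 in replicate 2 and 0.463 in the series-wide list. Wider clusters scored higher, with a Spearman correlation of width and score across clusters of 0.729, 0.695 and 0.602, although clusters are not independent replicates. Read depth is unknown.

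The first comparison the design holds is between the ChIP replicates. Most H3K9ac clusters of the shorter list recurred in the longer one: 6127 of the 6772 clusters of replicate 2, or 90.5%, overlapped a cluster of replicate 1. In the other direction, 5672 of the 8495 clusters of replicate 1, or 66.8%, overlapped a cluster of replicate 2. The bases covered in both replicates came to 15.7 Mb, a Jaccard index of 59.4%. Random placement of the clusters within their chromosomes gave 34.2%, 27.02% and 9.34% for these values on average. Each observed value exceeded the highest of 1000 placements, which was 35.8%, 28.2% and 10.0% (one-sided permutation p = 0.001 for each, the smallest that the placements can give).

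Recurrence in replicate 1 followed the score. Of its clusters in the highest score decile, 850 of 850 overlapped a replicate 2 cluster, and in the next decile 99.8% did. The share was 92.0% in the seventh decile and 57.4% in the fifth, and between 33.8% and 42.0% in the lowest 4 deciles. Clusters of replicate 2 recurred at 83.9% to 98.2% in each decile. The 2823 clusters of replicate 1 without a partner were narrower, with a median width of 1651 bp against 2782 bp for those with one. The 645 clusters of replicate 2 without a partner had a median width of 1481 bp against 2281 bp. Across the 5672 shared clusters of replicate 1, the score correlated with that of the best overlapping replicate 2 cluster with a Spearman coefficient of 0.827. Boundaries were close: among 4960 pairs in which each cluster overlapped just the other, starts lay a median of 119 bp apart and ends 122 bp apart. Replicate 1 was the wider in 3812 of these pairs, or 76.9%. Single clusters of replicate 1 spanned more than 1 cluster of replicate 2 in 481 cases, and the reverse held in 162.

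**Figure D1:**
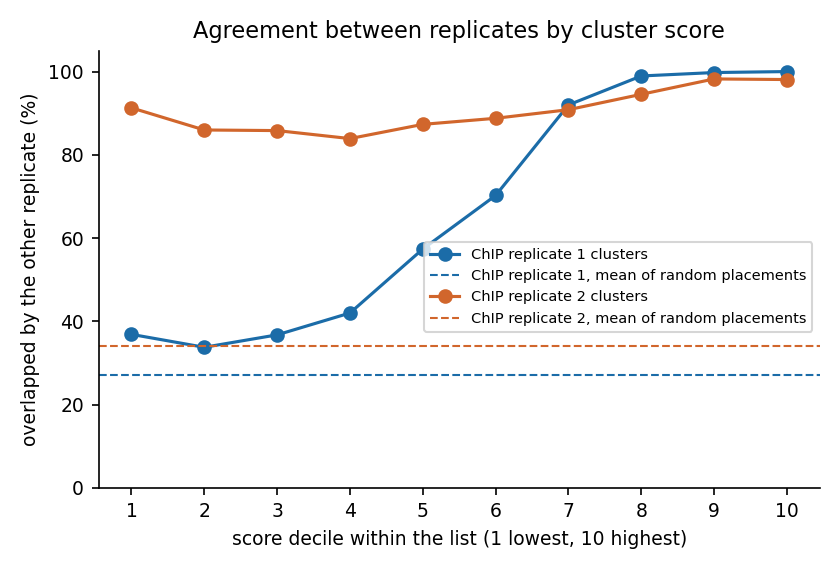
Share of the clusters of each ChIP replicate that overlapped a cluster of the other (vertical axis, %), by score decile within the list (horizontal axis, 10 highest). Points are deciles and dashed lines are the means of 1000 random placements of the whole list. The dashed lines are not matched to the cluster widths of a decile, which rise with score. Replicate 1 runs from 36.9% in its lowest decile to 100.0% in its highest, while replicate 2 stays at 83.9% or above.

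The series-wide list took in nearly all clusters of both replicates and added others. It overlapped 8443 of the 8495 clusters of replicate 1, or 99.4%, and 6696 of the 6772 clusters of replicate 2, or 98.9%. Of its own 12322 clusters, 5357 overlapped both replicates, or 43.5% (95% Wilson interval 42.6 to 44.4%). A further 2542, or 20.6%, overlapped replicate 1 alone, and 526, or 4.27%, overlapped replicate 2 alone. The remaining 3897, or 31.6% (30.8 to 32.5%), overlapped neither. Clusters found in both replicates were wide and high-scoring, with a median width of 3267 bp and a median score of 0.741. Those in neither had a median width of 1257 bp and a median score of 0.409. Clusters in replicate 1 alone had medians of 1881 bp and 0.406, and those in replicate 2 alone 1703 bp and 0.411. Their scores were thus like those of clusters in neither, and they were wider. The share overlapped by both fell to 22.96% when replicate clusters under the median score of their list were left out. The list was made from the same libraries, so its overlap with the replicates was not tested.

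Individual H3K9ac regions are named here by their position in release 5. The clusters of the series-wide list with the highest scores fell into 2 kinds. On the large arms, 7 of the 10 had a cluster in both replicates. The highest of these lay on 3L at 22068022 to 22071376, with a score of 2.87 in the series-wide list, 3.06 in replicate 1 and 2.88 in replicate 2. Next came 2L at 8040364 to 8044902, with 2.79, 2.93 and 2.83 in the same order, and 3R at 26032472 to 26035628, with 2.74, 3.00 and 2.66. The other 4 were on 2R at 12456498 to 12459674 and at 10102266 to 10105060, on 2L at 19007396 to 19010186, and on 3L at 1666694 to 1669628. Their series-wide scores were 2.55, 2.52, 2.54 and 2.46. The 3 remaining clusters lay on unplaced or heterochromatic sequence and overlapped a cluster of neither replicate. They were on U at 7530948 to 7533006, with the top score of the list at 3.54, on U at 4772116 to 4773116, with 2.86, and on 3LHet at 2137478 to 2138482, with 2.51.

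The widest domain of the series-wide list was a 43.3 kb cluster on 3R at 8062734 to 8106062. Replicate 1 covered 99.1% of it with 3 clusters and replicate 2 covered 78.9% with 7. A 38.3 kb domain on 2L at 640094 to 678426 was covered to 93.9% by 3 clusters of replicate 1 and to 45.1% by 6 of replicate 2. The next were 36.5 kb on 3R at 25077708 to 25114210, 35.5 kb on 3L at 22128620 to 22164164, and 34.8 kb on 2L at 15453394 to 15488164. Replicate 1 covered 96.5%, 90.5% and 90.1% of these, and replicate 2 covered 76.1%, 72.9% and 67.9%. The score of the widest domain was 0.865, well under those of the highest-scoring clusters.

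Of the clusters that a single replicate held, the highest-scoring 5 of replicate 1 included 3 on the X, at 11335 to 13090, 11487328 to 11488943 and 11634644 to 11636763, with scores of 1.12, 1.11 and 1.05. The others were on U at 6222003 to 6223344, with 1.38, and on 3L at 19479996 to 19482303, with 1.04. The 5 of replicate 2 lay largely on unplaced sequence: U at 9472517 to 9474701 with 3.78, U at 5537883 to 5539229 with 2.84, and U at 99126 to 100502 with 2.13. The other 2 were on 3L at 23663525 to 23665559, close to the centromere end of the assembled arm, with 3.65, and on YHet at 343174 to 345018, with 2.01. The first and the third of the U clusters of replicate 2 were not in the series-wide list either.

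Apart from the unplaced sequence U, H3K9ac clusters covered the autosome arms most, the X less, chromosome 4 less again and the heterochromatic scaffolds least. The sequence lengths used were not corrected for mappability. Coverage was 20.6% ± 4.87 of bases on 2R, 18.6% ± 4.43 on 3R, 17.2% ± 4.81 on 3L and 16.7% ± 4.68 on 2L (mean ± SD, n = 2 replicates here and below). It was 14.5% ± 3.02 on the X, 10.5% ± 0.327 on chromosome 4, a short and largely heterochromatic chromosome, and 0.972% ± 0.0263 on the heterochromatic scaffolds together. On U it was 0.233% ± 0.0307. The 5 large arms had this same order in each replicate and in the series-wide list. Relative to the autosome arms of the same list, the X had a coverage of 0.774 in replicate 1 and 0.831 in replicate 2, a mean ratio of 0.802 ± 0.0403, and 0.811 in the series-wide list. Over 1-Mb bins, coverage averaged 16.8% on the X and 21.6% on the autosomes in replicate 1 (two-sided permutation test over bins, p = 0.0035, adjusted p = 0.0053). The averages were 12.6% and 15.0% in replicate 2 (permutation p = 0.034, adjusted p = 0.034) and 23.9% and 29.4% in the series-wide list (p = 0.0065, adjusted p = 0.0078). The difference in mean coverage between X and autosomes was smaller than the SD of the autosome value between replicates, and it held within each list. It did not hold for strong clusters: with clusters at or above the median score of their list, the X to autosome ratio was 1.02.

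**Figure D2:**
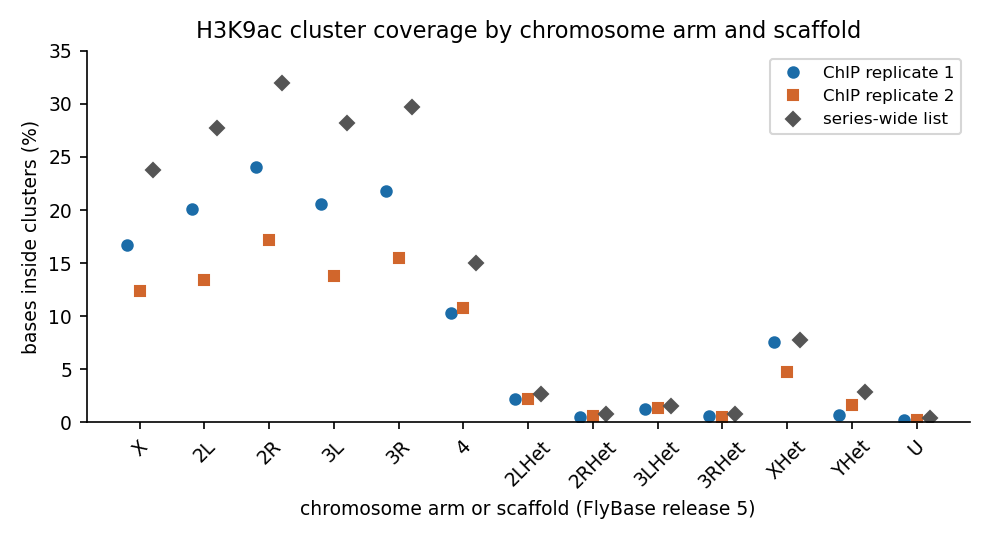
Share of bases inside H3K9ac clusters (vertical axis, %) on each chromosome arm and scaffold of release 5 (horizontal axis); circles are ChIP replicate 1, squares ChIP replicate 2 and diamonds the series-wide list. The X lies under each autosome arm in each list, and the scaffolds other than XHet lie under 3%.

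Clusters on the X ranked higher in score than those on the autosomes. Their median score percentile was 60.3 in replicate 1 and 65.0 in replicate 2, against 47.1 and 45.9 on the autosome arms, a difference of 16.1 ± 4.21 points. Over bins, the mean of the median percentiles was 61.7 on the X and 48.5 on the autosomes in replicate 1, and 66.0 and 47.3 in replicate 2. In the series-wide list these were 62.9 and 47.6. In each of the 3 lists, 22 of 22 X bins lay above the median of the 95 autosome bins (two-sided permutation test over bins, p = 2e-05, the smallest it can give, adjusted p = 4e-05). Per megabase, the X held 57.7 clusters in replicate 1 and 46.9 in replicate 2, against 73.4 and 58.0 on the autosome arms. Among clusters at or above the median score of their list, the X to autosome ratio of clusters per megabase was 1.06 in replicate 1 (95% interval 0.983 to 1.15) and 1.22 in replicate 2 (1.12 to 1.33). The interval for replicate 1 includes equal density.

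**Figure D3:**
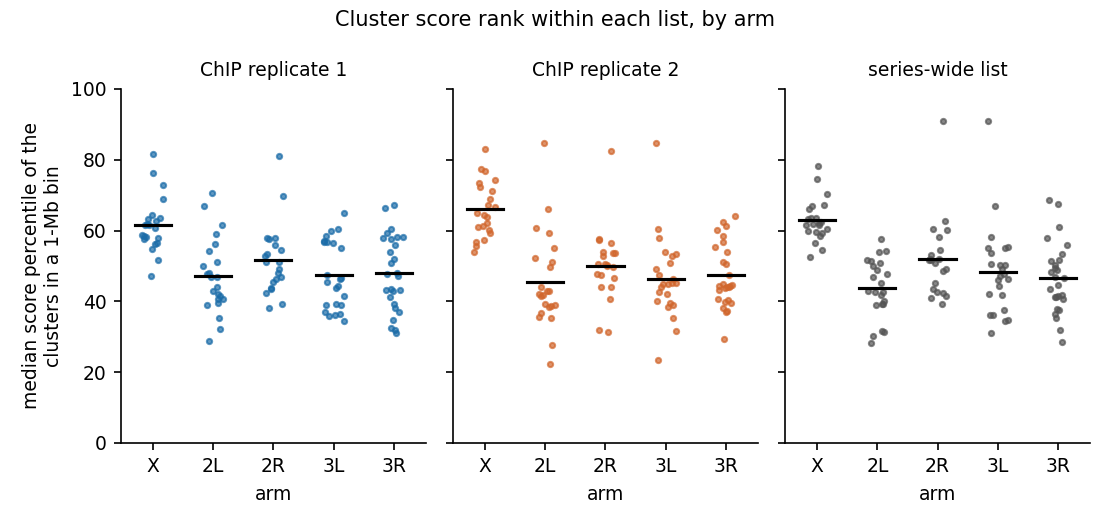
Median score percentile, within the list, of the clusters in each complete 1-Mb bin (vertical axis, 0 to 100) by large arm (horizontal axis), in one panel for each list; points are bins, spread sideways to be seen, and black lines are their means. X bins average 61.7, 66.0 and 62.9 in replicate 1, replicate 2 and the series-wide list.

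Chromosome 4 had a coverage of 10.3% in replicate 1 and 10.8% in replicate 2, while that of the autosome arms was 21.6% and 14.9%. Its ratio to the autosome arms was thus 0.478 in replicate 1 and 0.721 in replicate 2, from 62 and 67 clusters. The heterochromatic scaffolds had ratios of 0.0442 and 0.0663, from 38 and 39 clusters. Among the scaffolds, XHet was covered most, at 6.15% ± 1.95, while 2RHet had 0.541% ± 0.0803 and 3RHet 0.553% ± 0.0460. YHet held 1 cluster in replicate 1 and 3 in replicate 2.

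Along the arms, coverage was low at the centromere end of the assembled sequence on 4 of the 5 large arms. In the 1 Mb of assembled arm nearest the centromere it was 1.13% ± 0.149 on 3L, 3.74% ± 0.243 on 2R, 5.14% ± 0.937 on 2L and 6.71% ± 1.65 on the X. The arm 3R was the exception, with 22.9% ± 4.67 in the first 1 Mb of its assembled sequence. This was 1.21 times the rest of the arm in replicate 1 and 1.28 times in replicate 2. The heterochromatic scaffolds, such as 3RHet with 0.553% ± 0.0460, are separate sequences and not part of these stretches. The values therefore do not show coverage up to the centromere itself. Over the 5 arms together, the ratio of these stretches to the rest was 0.421 in replicate 1 and 0.471 in replicate 2. The comparison of these stretches was chosen after the data were examined. The least covered of the 117 complete bins was 3L at 23000001 to 24000000, with 2.04% ± 0.197. The most covered by the mean of the replicates were 2R at 19000001 to 20000000, with 31.9% ± 4.73, and its neighbour at 20000001 to 21000000, with 31.8% ± 4.53. In the series-wide list these had 46.0% and 46.6%, less than the 48.1% of 3L at 22000001 to 23000000. That 3L bin adjoins the least covered one and had 26.6% ± 9.32 over the replicates. On 3R, the bins at 25000001 to 26000000 and at 11000001 to 12000000 had 30.1% ± 5.88 and 28.7% ± 5.87. Coverage of bins correlated between the replicates with a Spearman coefficient of 0.925 across the 117 bins, which are not independent samples, and was higher in replicate 1 in 115 of them.

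**Figure D4:**
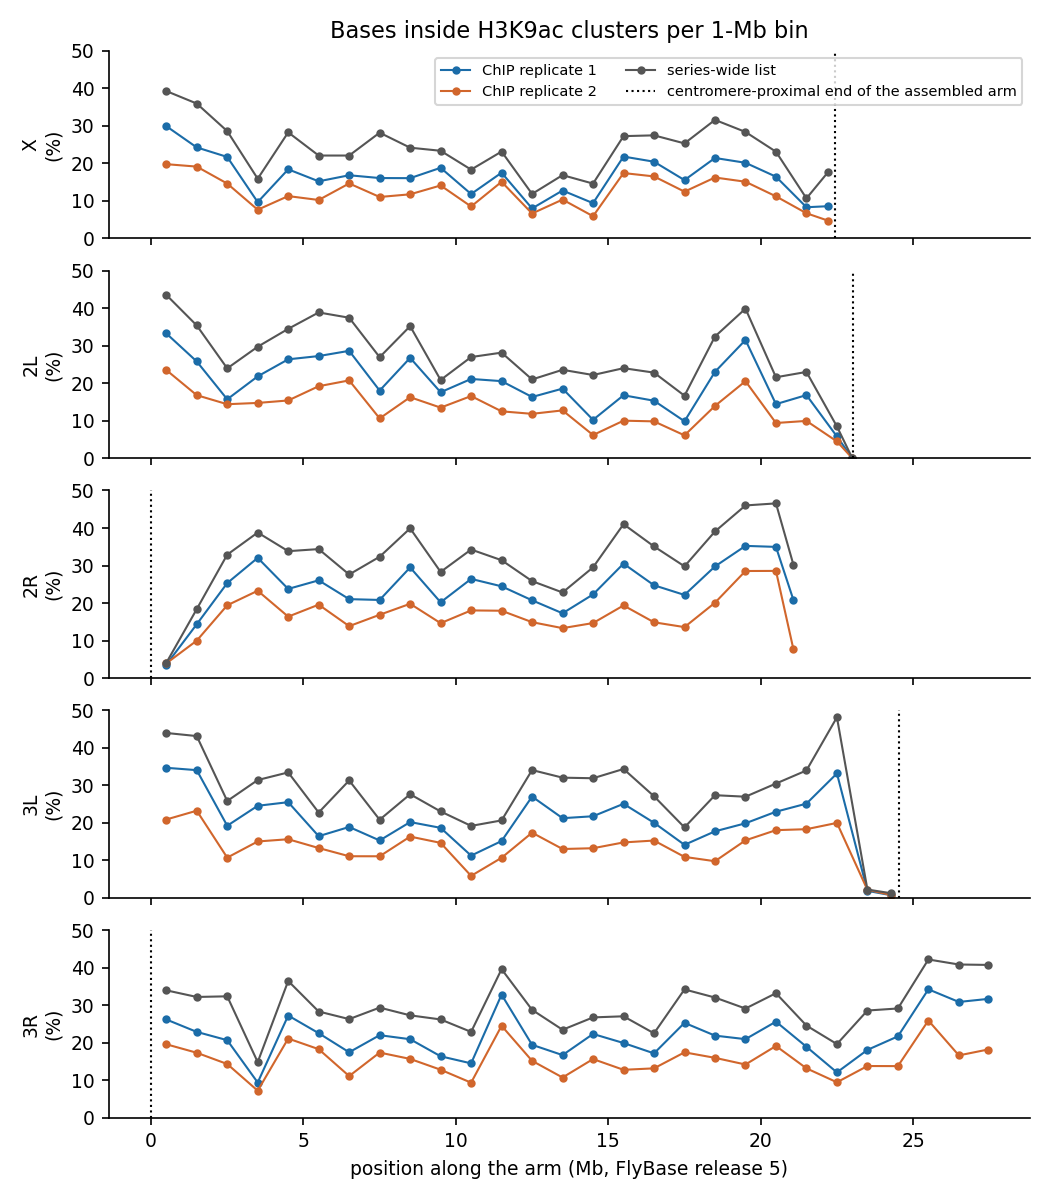
Share of bases inside H3K9ac clusters in bins of 1 Mb (vertical axes, %) along the 5 large arms in release 5 coordinates (horizontal axis, Mb), for both ChIP replicates and the series-wide list; the last bin of an arm is shorter, and dotted lines mark the end of the assembled arm next to the centromere. Coverage is low right at that end on X, 2L, 2R and 3L, and stands at 22.9% on average over the replicates in the first 1 Mb of 3R. On 3L the drop is abrupt, after 26.6% on average over the replicates in the bin at 22000001 to 23000000.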

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

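Some of the alternatives were chosen after the data were examined, among them placements that keep cluster spacing, replicate 1 shortened by score to the length of the replicate 2 list, and those named as added here. Agreement of the replicates stayed above chance (one-sided permutation p = 0.001) under each alternative run. The shares themselves moved. With replicate 1 shortened, 82.1% of replicate 2 and 74.8% of replicate 1 clusters were shared, in place of 90.5% and 66.8%, so the gap between the directions depends on list length. A 50% overlap gave 88.6% and 60.8%. In the counts that follow, an agreement setting is unmoved if it stayed above the placements with p under 0.05. Settings for agreement, the series-wide share, the score correlation and the X ratio were counted together. Of these, 17 left the value within its spread or on its side of the threshold, 5 moved it, and 1 took it across 1. With clusters at or above the median score, the ratio of X to autosome coverage changed from 0.802 to 1.02. The value of 1.02 is near equal coverage, so a reversal is not shown. Over all clusters, the ratio ranged from 0.774 to 0.831 without either replicate. The share of series-wide clusters overlapped by both replicates moved to 37.9% with a 50% overlap, to 22.96% with replicate clusters at or above their median score, which leaves fewer clusters to overlap, and, as an added alternative, to 54.2% for series-wide clusters as wide as the narrowest replicate cluster. The score correlation moved to 0.865 with a 50% reciprocal overlap and, added, to 0.794 from the side of replicate 2. Apart from fewer clusters, the cause was not tested. The settings for chromosome 4, heterochromatin, X score percentiles and the centromere-proximal ratio were all chosen after the data were examined. Of these, 9 gave values within the spread and 1 did not: the centromere-proximal ratio was 0.589 with 2 Mb. The 10 settings with a single replicate are left out of these counts, because with n = 2 neither value can leave the SD. Not run were the alternatives for transcription starts, marked genes and gene lists, which need an annotation of release 5. No paired analysis was possible because the inputs have no values of their own here and the results come from no test between groups. Depth is unknown, so what it limits could not be measured.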

Other observations

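Apart from the scale factor on X scores, the tests in this part were chosen after the values they concern had been seen.

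H3K9ac clusters lay closer together than chance would place them. On the large arms, the median gap between neighbours was 4081 bp in replicate 1, 5595 bp in replicate 2 and 2577 bp in the series-wide list, against means of 7717, 10491 and 4831 bp over random placements (one-sided permutation p = 0.001 for each, the smallest they can give). Gaps of at most 1000 bp made up 20.3% of those in replicate 1 and 15.9% in replicate 2, against 8.60% and 6.41% in the placements. The placements treat each cluster as a separate unit, although 481 clusters of replicate 1 spanned more than 1 cluster of replicate 2. How far domains split into several clusters add to the short gaps was not tested. Coverage was high over the outermost 1 Mb of X, 2L, 2R and 3L, on the side far from the centromere. In the last 1 Mb there it was 31.5% ± 5.74 on 2R, 28.4% ± 6.90 on 2L, 27.8% ± 9.75 on 3L, 24.8% ± 7.17 on the X and 22.9% ± 8.85 on 3R (mean ± SD, n = 2). These are 1.54, 1.70, 1.60, 1.69 and 1.20 times the coverage of the arm. On 3R the ratio was 1.34 in replicate 1 and 1.07 in replicate 2. Right at the end of 2R, at 21000001 to 21146708, coverage was 20.8% in replicate 1 and 7.66% in replicate 2. That was under the 24.0% and 17.2% of the whole arm.

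Stretches of over 100 kb without a cluster in any of the 3 lists numbered 44 on the large arms, of which 16 were on the X, 9 each on 2L and 3L, 6 on 2R and 4 on 3R. The longest was 491 kb on 3L at 23732603 to 24224043, near the centromere end of the assembled arm. It was followed by 344 kb on the X at 21501989 to 21845739 and 259 kb on 2R at 718655 to 977265. Among those named, 3R at 8582387 to 8786853, with 204 kb, was the one far from a centromere. Strong X clusters recurred less often than strong autosome clusters. Of replicate 1 clusters at or above the median score, 14.9% of those on the X (95% Wilson interval 12.6 to 17.4%) and 6.16% of those on the autosome arms (5.40 to 7.03%) had no partner in replicate 2. The shares without a partner in replicate 1 were 9.55% (7.63 to 11.9%) and 4.68% (3.93 to 5.56%) for replicate 2. Under the median score, the intervals for X and autosomes overlapped in both replicates.

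Clusters on the X ranked higher in score while the X was covered less. Wider X clusters account for no more than a part of the higher ranks. The difference in score percentile fell from 16.1 to 12.4 points within deciles of width, with 83.9% of it kept in replicate 1 and 72.1% in replicate 2. A lower yield of reads on the X may contribute, as the other replicate lacked more X than autosome clusters at or above the median score, by 6.78 percentage points on average. Loss of weak X clusters alone, which allows no excess of strong clusters on the X, cannot be told apart from it: in the top score decile the X to autosome ratio of clusters per megabase was 1.22 (95% interval 1.03 to 1.44) in replicate 1 and 1.44 (1.20 to 1.72) in replicate 2, but over the cutoffs at percentiles 50, 75 and 90 together, a one-sided permutation test over bins gave p = 0.1 in replicate 1 and 0.00645 in replicate 2. A common scale factor on X scores cannot be told apart either. The mean X to autosome score ratio was 1.05 at 5 clusters per Mb and 1.04 at 40, and above 1 in both replicates. Such alike values are what the planned rule looked for under a scale factor. They have no meaning as a factor without the zero of the score, so they do not decide it. As depth is unknown and the labels do not separate the sexes of the embryos, no biological explanation was tested.

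Of the series-wide clusters, 3897 overlapped neither replicate. The shorter minimum width of that list is not the whole cause, as 55.7% of them (95% Wilson interval 54.1 to 57.2%) were narrower than the narrowest replicate cluster. Most were narrow or weak: 6.44% (5.71 to 7.26%), or 251 clusters, were neither narrower than that nor under the median score of the list, while 4655 of the 5357 clusters in both replicates were neither. Among clusters in replicate 1 alone, 531 of 2542 were neither narrow nor weak, and 95 of 526 in replicate 2 alone. Most clusters in a single replicate were thus narrow or weak as well. Low score does not set them apart from clusters in a single replicate. Under the list median were 78.5% of those in neither, 77.8% in replicate 1 alone and 76.6% in replicate 2 alone. Width did differ: 7.63% and 15.8% of the clusters in replicate 1 alone and replicate 2 alone were narrower than the narrowest replicate cluster. Low score alone therefore does not tell why both replicates lacked a cluster. How the replicates were combined is not given in the sources used here, and no biological explanation was tested.

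The coverage of chromosome 4 was kept in replicate 2, at 1.04 times that of replicate 1, while that of the autosome arms was 0.693 times; the heterochromatic scaffolds together had 1.04 but went both ways, with 0.634 on XHet, 0.889 on 3RHet and 2.54 on YHet. A shorter list that holds the stronger clusters does not account for this on chromosome 4: replicate 1 shortened by score to the length of the replicate 2 list had a ratio to the autosome arms of 0.405, with an upper counting limit of 0.550, against 0.478 for the full list and 0.721 in replicate 2. Taking clusters as independent, those without a partner argue against counting error on chromosome 4, while the total counts do not. Its total counts did not pass 0.05 against the arms (two-sided Fisher's exact test, p = 0.0901), but that test ignores that most loci are in both lists. The clusters without a partner numbered 10 in replicate 1 and 16 in replicate 2, against 2403 and 513 on the autosome arms (two-sided Fisher's exact test, p = 8.69e-07). Chromosome 4 was chosen after its value was seen, so this p is too small. Of the 16, 15 scored under the median of the replicate 2 list. The median score percentile of chromosome 4 clusters was 44.6 in replicate 1 and 28.6 in replicate 2. The kept coverage thus includes weak clusters that did not recur. On the scaffolds neither explanation can be excluded: the shortened list gave 0.0437, with an upper limit of 0.0620 that includes the value of 0.0553 midway between the replicates, and counting error cannot be told apart, with exact p = 0.252 for total counts, 0.00624 for the 5 and 6 clusters without a partner, and 0.0578 for these without YHet. What sets chromosome 4 apart stays open, and no biological explanation was tested.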
